A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

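RNA abundance was measured on Affymetrix yeast arrays in 12 samples of S. cerevisiae, 3 biological replicates for each of 4 groups named by GEO's labels as wild type, nup60 deletion, ada2 deletion and the deletion of both genes. The labels give every strain the genotype MATa his3 leu2 met15 ura3, with a kanamycin resistance marker in place of each deleted gene. Cultures of 50 mL in rich medium were grown to mid-log phase, and total RNA was extracted with TRIzol and glass beads, per the labels' protocols. Biotin-labelled RNA was prepared from 5 µg of total RNA, per the labels' protocols. The values used were the deposited intensities per probe set, which came from Affymetrix Expression Console 1.1 and RMA, per the submitters' processing notes. These deposited intensity values were on a linear scale, between 11.4 and 51828, with column medians from 158.2 to 243.9. The design had assumed log2 RMA values, and log2 was therefore taken here of the deposited intensities. No other normalization was applied in the principal fit.

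The values covered 10928 probe sets. Of these, 213 control probe sets (166 for spikes, ribosomal RNA and housekeeping genes and 47 for reporter sequences) were kept apart. Another 1746 probe sets belong to a second yeast, S. pombe, and their array means gave a background level, the 95th percentile, of 5.62 on the log2 scale. A further 3470 probe sets had no gene in the pairing table, and 1 probe set that named several genes was left out. The remaining 5498 probe sets stood for 5449 genes, since 47 genes had more than 1 probe set and the one with the highest mean was used. Of the genes tested, 115 had a probe set whose suffix marks sequence shared with other transcripts. Gene names and neighbours came from a RefSeq table of assembly release 64, and no genome sequence was used. Signal over background sets the depth of an array: 105 to 148 genes per array were below the background level, and a fold against a group below it is given as a bound.

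Genes were tested with limma 3.58.1 in R 4.3.3, with a mean per group, all 12 arrays and empirical Bayes moderation (8 residual and 2.58 prior degrees of freedom). There were 6 comparisons, namely each deletion against wild type, the labelled double deletion against each single deletion, and the interaction, the departure from the sum of single effects on the log2 scale. A gene passed at a Benjamini-Hochberg adjusted p below 0.05 within its comparison, and errors are standard errors. Gene lists, 47 in number and written from general knowledge before the data were examined, were tested with limma camera at a preset correlation between genes of 0.01, and 45 of them had the minimum of 5 measured genes. A list that is part of these counts is not reported here. Each list's p was also computed with an estimated correlation, and its members were counted with p adjusted over all genes and over the list alone. The same test was applied to 16 chromosomes. Tables were made in R and figures with Python 3.11.15.

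Genes named in the text followed a rule fixed before the data were examined. It took the deleted genes, their neighbours and the marker genes. Among genes that passed and whose 3 arrays of a group all lay above the 3 of the other, it took the 10 largest rises and the 10 largest falls against wild type. For the comparisons with a single deletion and for the interaction it took the 5 largest in each direction, without the separation condition. It also took up to 4 members with the largest change of each list that passed. The genes of the mating-type loci and pheromones in the label check were added after their values were seen.

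Alternatives fixed in advance were centring on the array median, a second quantile normalization, removal of dim genes, an intensity trend, robust moderation, array weights, fits of only the groups compared, the mean of all probe sets, removal of probe sets with shared sequence, a replicate block, an estimated correlation between genes, and leaving out each array. Alternatives chosen after seeing the data were a fit without wild-type array 1 and array 3 labelled as the double deletion, a poly-A spike covariate, and the removal of deleted genes, URA3 and mating lists from the correlation and slope. The procedure was tested on simulated data with the variances of these arrays and 200 changed genes. At log2 changes of 0.25, 0.5 and 1, a comparison of 3 with 3 arrays recovered 50.5%, 89% and 100% of them, and the interaction 24.5%, 71% and 95.5%, with 3 to 18 false calls per setting. A simulated shift of -0.25 in a list was recovered, and no other list was called. Noise was drawn independently for each gene, so these results do not show how gene counts or list tests behave where genes are correlated. The raw scans were not used here.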

Results

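RNA abundance was measured in 4 strains of budding yeast, Saccharomyces cerevisiae, with 3 biological replicates each and 1 Affymetrix array per replicate. The strains were labelled as wild type, a deletion of NUP60, a deletion of ADA2, and a deletion of both genes. NUP60 encodes a protein of the nuclear basket of the nuclear pore complex, and ADA2 encodes a subunit of the SAGA histone acetyltransferase complex. Cells were grown at 30 °C in 50 mL of rich medium and collected in mid-log phase. Of 10928 probe sets, those of 5449 S. cerevisiae genes were tested. The median log2 intensity of these genes lay between 11.21 and 11.28 on the 12 arrays. Between 105 and 148 genes per array were below a background level of 5.62. Within a group, the lowest correlation between arrays across genes was 0.993. Array 1 of the wild type and array 3 of those labelled as the double deletion stood apart in their control probes, with mean log2 poly-A spike levels of 8.95 and 9.14 against 6.74 to 7.99 on the other arrays. The number of arrays limits the precision of all values. With 1 strain per group, the effect of a deletion cannot be told apart from other differences of its strain. Errors of log2 fold changes are standard errors from limma, with n = 3 arrays per group.

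The deleted genes were read in every array first, as a check of the labels. NUP60 had a mean log2 intensity of 12.53 ± 0.04 (SD, n = 3) in wild type and 12.23 ± 0.04 in the ada2 arrays. It stood at 6.37 ± 0.18 in the nup60 arrays and 6.20 ± 0.16 in the arrays labelled as the double deletion. ADA2 had 10.95 ± 0.02 in wild type and 10.72 ± 0.02 in the nup60 arrays, against 4.23 ± 0.19 in the ada2 arrays and 4.39 ± 0.16 in the arrays labelled as the double deletion. Both deleted genes were therefore low in every array whose label names them. Other genes went against the labelled genotype, which was MATa and ura3 for all strains. URA3 was below background in wild type, nup60 and ada2 (4.59, 4.38 and 4.48) and at 12.77 ± 0.35 in the arrays labelled as the double deletion. HMRA1, the a1 gene made in a cells, was at 11.47, 11.17 and 11.32 in the other groups and at 4.38 ± 0.10 in these arrays. HMLALPHA1, the alpha1 gene made in alpha cells, was below background in the other groups (4.73, 4.88 and 5.02) and at 11.73 ± 0.11 in these arrays. The pheromone gene MF(ALPHA)1 was at 4.78, 4.95 and 5.19 against 14.51 ± 0.14. Among the other marker genes, group means were 12.42 to 12.53 for HIS3, 6.14 to 6.70 for LEU2 and 4.90 to 5.08, below background, for MET17. HIS3 was thus high in every group although the labels name all strains his3, so a marker's signal alone does not show a wrong label. URA3 stood apart by its difference between groups. Given the values of URA3, HMRA1, HMLALPHA1 and MF(ALPHA)1, any comparison with the arrays labelled as the double deletion also compared URA3 and mating types, as read from these transcripts.

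**Figure D1:**
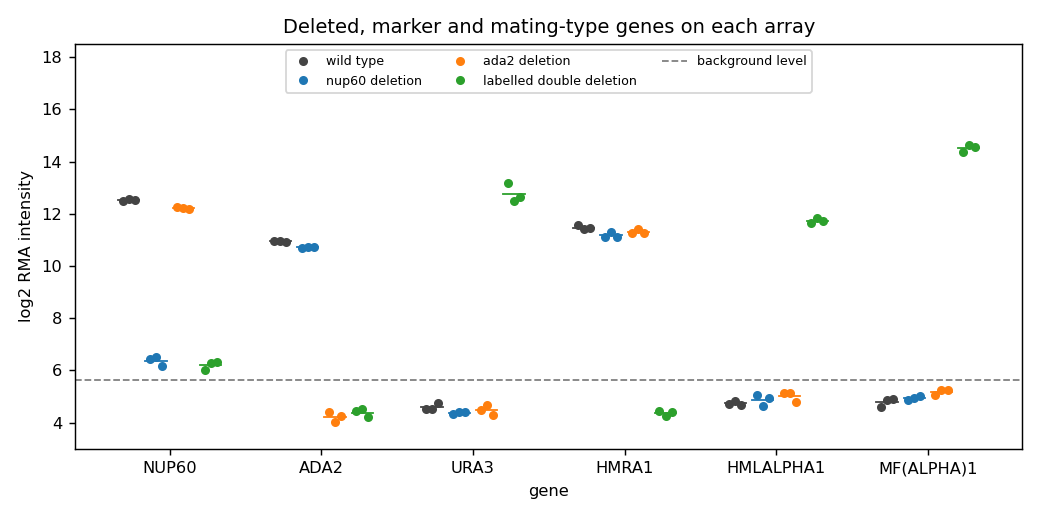
Log2 RMA intensity (vertical axis) of 6 genes (horizontal axis) on each of the 12 arrays, with points for arrays, colours for the 4 groups, short lines for group means and a dashed line at the background level of 5.62. In the arrays labelled as the double deletion, URA3 averaged 12.77 and HMRA1 averaged 4.38, while wild type averaged 4.59 and 11.47.

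The comparison of nup60 with wild type asked which transcripts differed in the strain without NUP60. Genes of the general stress response rose. The largest rise was that of DDR2, by 3.79 ± 0.088 on the log2 scale (limma adjusted p = 2.04e-10), followed by the small heat shock protein gene HSP26 (3.39 ± 0.058) and HSP12 (3.32 ± 0.062). SOL4 rose by 3.25 ± 0.077, NCA3 by 3.04 ± 0.14, FMP16 by 2.96 ± 0.12, the cell wall protein gene PIR3 by 2.85 ± 0.086, TMA10 by 2.85 ± 0.093 and RIM4, a regulator of meiosis, by 2.80 ± 0.090. HUG1, an inhibitor of ribonucleotide reductase that is induced by DNA damage, rose by 2.99 ± 0.073. After NUP60 itself (-6.16 ± 0.091), the largest falls were those of the IMP dehydrogenase gene IMD2 (-2.46 ± 0.085), whose probe set can also detect related genes, and of FCY21 (-1.54 ± 0.075). AAC3 came next, at 10.69 to 10.78 on the wild-type arrays and 9.69 to 9.82 on the nup60 arrays. Smaller falls were those of ZRT1 (-0.96), YHK8 (-0.94), PRY3 (-0.94), ATF2 (-0.91), HXT1 (-0.88) and ANB1 (-0.87). The 10 largest rises and the 10 largest falls of each deletion against wild type were taken only from genes whose 3 arrays of a group all lay above the 3 of the other. Of 5449 genes, 1369 rose and 1429 fell at an adjusted p below 0.05 (51.3%). Changes of at least 2-fold comprised 142 rises and 3 falls, with NUP60 itself among the falls. The neighbours of NUP60, TFC3 and ERP1, did not pass (limma adjusted p = 0.346 and 0.337).

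Of 45 gene lists tested, all fixed before the data were examined, 20 passed camera in the nup60 arrays, 12 upward and 8 downward, and 4 of them also with an estimated correlation. The general stress response (61 of 63 up and 1 down, the same adjusted over the list alone, median 1.25) had a camera adjusted p of 1.12e-35, and 0.0241 with an estimated correlation. The DNA damage response (18 of 27 up, with 20 adjusted over the list alone, median 0.23) included RNR3 (1.58 ± 0.069), PLM2 (1.27 ± 0.061) and UBI4 (1.12 ± 0.065). Its adjusted p was 2.18e-06, and 0.0357 with an estimated correlation. Glucose-repressed carbon metabolism (21 of 34 up and 4 down, with 22 and 4 adjusted over the list alone, median 0.33) included CRC1 (1.96 ± 0.11), NDE2 (1.79 ± 0.13) and MTH1 (1.15 ± 0.064), at an adjusted p of 9.03e-05, and 0.0357 with an estimated correlation. Ribosome biogenesis genes fell (59 of 64 down, with 62 adjusted over the list alone, median -0.33), among them UTP20 (-0.79 ± 0.10) and RRP5 (-0.63 ± 0.15), at an adjusted p of 1.55e-14, and 0.0458 with an estimated correlation. Wild-type array 1, which stood apart in its control probes, lay above wild-type arrays 2 and 3 by medians of 0.15 and 0.098 over the DNA damage and ribosome biogenesis lists. The medians of these lists were 0.33 and -0.32 without it and array 3 labelled as the double deletion, a fit chosen after seeing the data. UTP20 was at 12.81 on that array and at most 12.43 on wild-type arrays 2 and 3.

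The other lists that passed in the nup60 arrays did so only with the preset correlation. Respiratory chain and ATP synthase genes (37 of 38 up, with 38 adjusted over the list alone, median 0.35) and TCA cycle genes (12 of 16 up, the same adjusted over the list alone, median 0.46) shifted upward, and SDH2, a member of both lists, rose. Their adjusted p was 0.146 and 0.146 with an estimated correlation. Mitochondrial ribosomal proteins (39 of 67 up, with 43 adjusted over the list alone, median 0.17) and the proteasome (27 of 35 up, with 30 adjusted over the list alone, median 0.16) also shifted upward, with RPN4, the activator of proteasome genes, at 0.56 ± 0.037. Their adjusted p was 0.284 and 0.0674 with an estimated correlation. Among Hsf1 chaperones (16 of 25 up and 1 down, the same adjusted over the list alone, median 0.24) HSP42 rose by 2.07 ± 0.077 and SSA4 by 1.44 ± 0.088, and among cell wall genes (19 of 42 up and 3 down, the same adjusted over the list alone, median 0.088) SPI1 rose by 1.89 ± 0.083 and GSC2 by 1.85 ± 0.053. These lists had an adjusted p of 0.0525 and 0.242 with an estimated correlation. Genes known to be recruited to the nuclear pore (8 of 13 up and 1 down, the same adjusted over the list alone, median 0.25) included HXK1 (2.48 ± 0.042) and CTT1 (1.68 ± 0.088), and G2/M genes (10 of 19 up, the same adjusted over the list alone, median 0.19) included SPO12 (0.76 ± 0.053). With an estimated correlation their adjusted p was 0.146 and 0.236. Meiosis and sporulation genes (15 of 42 up and 4 down, the same adjusted over the list alone, median 0.17) had an adjusted p of 0.528 with an estimated correlation. Their call was lost without wild-type array 2 (limma camera adjusted p = 0.0567), wild-type array 3 (0.0798) or nup60 array 2 (0.0563). Under quantile normalization their median was 0.018. G2/M and meiosis genes lay 0.13 and 0.22 higher in the median on wild-type array 1 than on arrays 2 and 3, and without it and array 3 labelled as the double deletion these lists had medians of 0.25 and 0.22.

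Downward lists in the nup60 arrays concerned the nuclear pore, SAGA, silencing and biosynthesis. Nuclear pore complex genes (21 of 33 down, the same adjusted over the list alone, median -0.24), a list that holds NUP60, included POM152 (-0.41 ± 0.063) and NUP120 (-0.41 ± 0.083). SAGA subunit genes (8 of 19 down, the same adjusted over the list alone, median -0.18) included TRA1 (-0.69 ± 0.13) and SPT8 (-0.34 ± 0.071), and genes of silencing by SIR proteins (10 of 20 down, the same adjusted over the list alone, median -0.19) included ORC1 (-0.43 ± 0.085). These 3 lists had an adjusted p of 0.415, 0.146 and 0.303 with an estimated correlation. Nuclear transport and mRNA export genes (17 of 40 down and 4 up, with 19 and 5 adjusted over the list alone, median -0.13) had an adjusted p of 0.483 with an estimated correlation, and GSP2 rose by 1.43 ± 0.034 among them. Gcn4-regulated amino acid genes (27 of 52 down and 7 up, with 30 and 7 adjusted over the list alone, median -0.16), purine biosynthesis (12 of 22 down and 2 up, with 13 and 2 adjusted over the list alone, median -0.16) and cytosolic ribosomal proteins (31 of 128 down, with 24 adjusted over the list alone, median -0.050) had an adjusted p of 0.146, 0.236 and 0.404 with an estimated correlation. LYS4 stood at -0.54 ± 0.050, IMD3 at -0.49 ± 0.054 and RPS9A at -0.59 ± 0.072. Under quantile normalization 5 lists no longer passed, namely SAGA subunits, purine biosynthesis, meiosis and sporulation, nuclear transport, and cytosolic ribosomal proteins (limma camera adjusted p = 0.0768, 0.085, 0.633, 0.109 and 0.0741). Their medians were then -0.18, -0.14, 0.018, -0.14 and -0.029. On wild-type array 1 the nuclear pore, silencing and nuclear transport genes lay 0.17, 0.23 and 0.070 above arrays 2 and 3 in the median, and without it and array 3 labelled as the double deletion the list medians were -0.17, -0.12 and -0.10. NUP120, TRA1 and ORC1 were at 11.40, 12.04 and 11.55 on that array and at most 11.07, 11.71 and 11.21 on wild-type arrays 2 and 3. Among lists that did not pass, subtelomeric genes, G1/S genes and glycolysis had a median, mean and test that differed in sign.

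The comparison of ada2 with wild type asked which transcripts differed in the strain without ADA2. The mating genes BAR1, FUS1 and MFA1 fell, and the arginine biosynthesis genes ARG3 and ARG1 rose. BAR1, which encodes a protease that degrades alpha factor, fell by 2.93 ± 0.072 (limma adjusted p = 7.85e-10), the cell fusion gene FUS1 fell by 2.76 ± 0.094, and the a-factor gene MFA1 fell by 2.71 ± 0.074. FAR1 fell by 2.77 ± 0.12 and AFB1 fell by 2.44 ± 0.098. ARG3 rose by 3.21 ± 0.099 (limma adjusted p = 2.12e-09) and ARG1 by 2.46 ± 0.070. Further rises were those of HSP12 (2.16 ± 0.062), RTC2 (2.12 ± 0.079), SGA1 (2.09 ± 0.053), CLD1 (2.08 ± 0.064), BNA2 (2.05 ± 0.044), ECM13 (2.02 ± 0.17) and TIR3 (1.97 ± 0.073). FMP48 rose as well, with 7.96 to 8.10 on the wild-type arrays and 9.99 to 10.12 on the ada2 arrays. Further falls were those of YGR109W-A (-3.92 ± 0.15), whose probe set can detect several copies of a sequence, YGP1 (-3.91 ± 0.12), PHO3 (-2.88 ± 0.10) and YRO2 (-2.23 ± 0.10). ADA2 itself was below background and at least 40.1-fold lower. Of 5449 genes, 1237 rose and 1254 fell (45.7%), with 68 rises and 58 falls of at least 2-fold. UTP6, a neighbour of ADA2, fell by 0.27 ± 0.039 here and also in the nup60 arrays, where it fell by 0.20 ± 0.039. The call of RPS17B, the other neighbour, was lost with a replicate block (-0.099, limma adjusted p = 0.0667) and after centring (-0.07, 0.183). NUP60 fell by 0.30 ± 0.091 (limma adjusted p = 0.0204), a call lost without wild-type array 2 (0.0593), ada2 array 2 (0.0511) or ada2 array 3 (0.0648).

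In the ada2 arrays 18 of the 45 lists passed camera, 8 upward and 10 downward, and 1 of them also with an estimated correlation. That list was glucose-repressed carbon metabolism (24 of 34 up and 2 down, with 26 and 3 adjusted over the list alone, median 0.35), at an adjusted p of 6.73e-06, and 0.0382 with an estimated correlation. CAT8 rose by 1.90 ± 0.11 and SIP4 by 1.17 ± 0.093. The a-specific genes (7 of 7 down, the same adjusted over the list alone, median -0.97) had an adjusted p of 6.73e-06 and included AGA2 (-1.45 ± 0.087) and STE6 (-0.97 ± 0.12). The mating pheromone response (17 of 24 down and 2 up, with 18 and 3 adjusted over the list alone, median -0.66) included SST2 (-1.84 ± 0.083), and haploid-specific genes (8 of 12 down, the same adjusted over the list alone, median -0.52) included HO (-1.34 ± 0.058), FUS3 (-1.14 ± 0.099) and GPA1 (-0.91 ± 0.044). These 3 mating lists had an adjusted p of 0.26, 0.26 and 0.269 with an estimated correlation. In the same arrays HMRA1 stayed at 11.32 and URA3 at 4.48, as in MATa ura3 cells. Pheromone and haploid-specific genes lay 0.092 and 0.11 higher in the median on wild-type array 1 than on arrays 2 and 3, and without it and array 3 labelled as the double deletion their medians were -0.62 and -0.41.

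General stress genes shifted upward in the ada2 arrays too (38 of 63 up and 7 down, with 38 and 8 adjusted over the list alone, median 0.24), with HSP26 at 1.70 ± 0.058, while Hsf1 chaperones shifted downward (14 of 25 down and 1 up, with 15 and 1 adjusted over the list alone, median -0.19), with BTN2 at -1.16 ± 0.083 and HSP82 at -0.69 ± 0.049. Their adjusted p was 0.269 and 0.124 with an estimated correlation. Gcn4-regulated genes (26 of 52 up and 10 down, the same adjusted over the list alone, median 0.13) held both ARG3 and a fall of LEU9 (-1.30 ± 0.064), at an adjusted p of 0.291 with an estimated correlation. Pore-recruited genes (10 of 13 up and 2 down, the same adjusted over the list alone, median 0.35), glycolysis (8 of 16 up, the same adjusted over the list alone, median 0.085) and the respiratory chain (25 of 38 up and 3 down, with 26 and 3 adjusted over the list alone, median 0.21) shifted upward. An estimated correlation gave an adjusted p of 0.26, 0.26 and 0.447. HXK1 rose by 1.47 ± 0.042 and TDH1 by 0.72 ± 0.063. Seripauperin genes (7 of 13 up, with 8 adjusted over the list alone, median 0.25) included PAU3 (0.60 ± 0.065), and subtelomeric genes (81 of 227 up and 34 down, the same adjusted over the list alone, median 0.082) included SNO4 (1.74 ± 0.072). The adjusted p rose to 0.26 and 0.354 with an estimated correlation.

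Ribosome biogenesis (29 of 64 down, the same adjusted over the list alone, median -0.17), cytosolic ribosomal proteins (39 of 128 down and 1 up, with 20 and 1 adjusted over the list alone, median -0.061) and mitochondrial ribosomal proteins (23 of 67 down and 5 up, the same adjusted over the list alone, median -0.11) shifted downward in the ada2 arrays. With an estimated correlation their adjusted p was 0.26, 0.413 and 0.579. G1/S genes (14 of 35 down and 4 up, the same adjusted over the list alone, median -0.10) included CLB6 (-1.09 ± 0.038), and multidrug resistance genes (11 of 22 down and 3 up, the same adjusted over the list alone, median -0.25) included QDR2 (-1.38 ± 0.071). Both had an adjusted p of 0.354 with an estimated correlation. Ribosome biogenesis and multidrug genes lay 0.098 and 0.10 higher in the median on wild-type array 1 than on arrays 2 and 3, and without it and array 3 labelled as the double deletion their medians were -0.12 and -0.21. Proteasome genes (10 of 35 down, the same adjusted over the list alone, median -0.073) had an adjusted p of 0.354 with an estimated correlation. The proteasome call was lost with arrays centred on their median (limma camera adjusted p = 0.0603), under quantile normalization (0.145), without wild-type array 2 (0.0537) and without wild-type array 3 (0.0897), and its median was -0.042 under quantile normalization. Among lists that did not pass, the cell wall, purine, unfolded protein, iron, phospholipid and chromatin remodelling lists had a median, mean and test that differed in sign.

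Whether both single deletions moved the same genes was read from their fold changes against the shared wild-type arrays, across genes, which are not independent replicates. The Pearson correlation was 0.312, and unchanged groups simulated against those controls gave a median of 0.43 with a central 95% from -0.404 to 0.961 over 100 draws. The covariance was 0.0476 against a simulated median of 0.0019 (central 95% from -0.0029 to 0.0218). Genes that rose in both numbered 617 against 310.8 for independent lists, and genes that fell in both numbered 518 against 328.9. In opposite directions, 244 genes rose in nup60 and fell in ada2 (315.1 for independent lists), and 177 did the reverse (324.4). The 3 wild-type arrays could not be split into parts of at least 2, so part of the excess may come from the shared controls.

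In the arrays labelled as the double deletion, mating-type genes and URA3 showed the largest changes against wild type. MF(ALPHA)1 was at least 475-fold higher, URA3 at least 142-fold and HMLALPHA1 at least 69.3-fold higher, while HMRA1 was at least 57.5-fold and ADA2 at least 40.1-fold lower. MF(ALPHA)2 rose by 6.80 ± 0.11 (limma adjusted p = 2.58e-12) and the a-factor receptor gene STE3 by 4.62 ± 0.067. Outside these genes, RIM4 rose by 4.64 ± 0.090, HSP26 by 4.14 ± 0.058, YPS6 by 4.14 ± 0.096, YIR042C by 4.09 ± 0.26 and ECM13 by 4.01 ± 0.17. NUP60 fell by 6.33 ± 0.091, IMD2 fell by 3.91 ± 0.085, BAR1 fell by 3.85 ± 0.072 and MFA2 fell by 3.66 ± 0.063. Other falls were those of the metal transporter gene FET4 (-3.44 ± 0.12), YMR230W-A (-3.06 ± 0.076), ARO10 (-2.95 ± 0.10) and HXT1 (-2.81 ± 0.10). Of 5449 genes, 1968 rose and 2023 fell (73.2%), with 404 rises and 126 falls of at least 2-fold. Of the neighbours, ERP1 rose by 0.20 ± 0.039, RPS17B fell by 0.24 ± 0.035 and UTP6 fell by 0.48 ± 0.039. A total of 588 genes rose and 492 fell in all 3 comparisons with wild type, and 947 passed in this comparison and in neither single deletion.

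Glucose-repressed carbon metabolism genes rose in the arrays labelled as the double deletion. Of the 45 lists, 23 passed camera, 14 upward and 9 downward, and 1 also with an estimated correlation. This was glucose-repressed carbon metabolism (28 of 34 up and 3 down, the same adjusted over the list alone, median 1.17), at an adjusted p of 7.41e-07, and 0.029 with an estimated correlation. In it NDE2 rose by 2.82 ± 0.13, CRC1 by 2.64 ± 0.11 and CAT8 by 2.63 ± 0.11, and POT1 was at least 9.68-fold higher. Respiratory chain and ATP synthase genes (38 of 38 up, the same adjusted over the list alone, median 1.09) and TCA cycle genes (16 of 16 up, the same adjusted over the list alone, median 0.91) included INH1 (2.15 ± 0.069), SDH2 (2.02 ± 0.073) and CIT3 (1.65 ± 0.057). Their adjusted p was 4.07e-15 and 5.31e-07, and 0.128 and 0.128 with an estimated correlation. General stress genes (58 of 63 up and 2 down, the same adjusted over the list alone, median 1.34) included XBP1 (3.74 ± 0.16) and HSP30 (3.45 ± 0.071), and DNA damage genes (21 of 27 up and 2 down, the same adjusted over the list alone, median 0.48) included HUG1 (2.35 ± 0.073). Ribosome biogenesis genes fell (63 of 64 down, the same adjusted over the list alone, median -0.60), with DBP2 at -1.10 ± 0.066. SAGA subunit genes (14 of 19 down, the same adjusted over the list alone, median -0.33), a list that holds ADA2, included TAF6 (-0.70 ± 0.069). Each of these 4 lists had an adjusted p of 0.0626 with an estimated correlation. DNA damage and ribosome biogenesis genes had medians of 0.49 and -0.59 without wild-type array 1, on which they stood higher, and array 3 labelled as the double deletion.

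Mating lists were read in the arrays labelled as the double deletion with their alpha-cell and URA3 transcripts in view. The a-specific genes (7 of 7 down, the same adjusted over the list alone, median -2.61) had an adjusted p of 2.67e-05, and the pheromone response (16 of 24 up and 5 down, the same adjusted over the list alone, median 0.40) included AGA1 (1.94 ± 0.11). With an estimated correlation the adjusted p was 0.128 and 0.404. Seripauperin genes (10 of 13 up and 1 down, the same adjusted over the list alone, median 0.75) included PAU3 (2.36 ± 0.065) and PAU5 (1.29 ± 0.066). COS genes (7 of 9 up and 1 down, the same adjusted over the list alone, median 0.63) included COS12 (2.63 ± 0.23) and COS111 (2.28 ± 0.11). Subtelomeric genes, the outermost 10 reading frames of each arm (120 of 227 up and 48 down, the same adjusted over the list alone, median 0.30), included YPS6. The adjusted p of these 3 lists was 0.00246, 0.0377 and 0.000775, and 0.128, 0.154 and 0.184 with an estimated correlation.

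**Figure D2:**
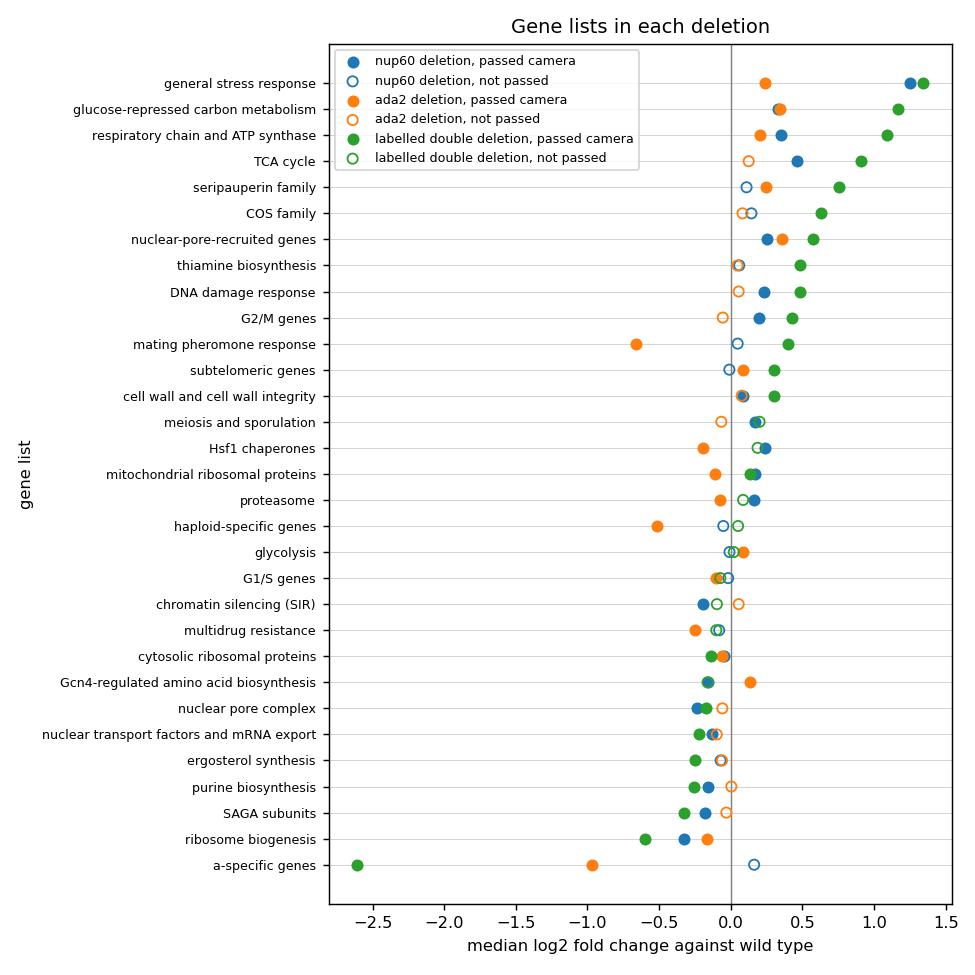
Median log2 fold change against wild type (horizontal axis) of each gene list given here that passed camera in at least 1 deletion (vertical axis), with colours for the 3 deletions, filled points where the list passed and open points where it did not. General stress genes had medians of 1.25, 0.24 and 1.34 in the nup60, ada2 and labelled double-deletion arrays, and ribosome biogenesis -0.33, -0.17 and -0.60.

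Further upward lists in the arrays labelled as the double deletion were thiamine biosynthesis (12 of 16 up and 3 down, the same adjusted over the list alone, median 0.49), G2/M genes (12 of 19 up and 1 down, the same adjusted over the list alone, median 0.43) and cell wall genes (28 of 42 up and 8 down, the same adjusted over the list alone, median 0.30). They included THI13 (1.83 ± 0.050), SPO12 (1.13 ± 0.053) and GSC2 (2.38 ± 0.053), and had an adjusted p of 0.207, 0.208 and 0.258 with an estimated correlation. Pore-recruited genes (10 of 13 up and 2 down, the same adjusted over the list alone, median 0.57) included HXK1 (3.13 ± 0.042), while the a-factor gene MFA2, also on this list, fell with the other a-specific genes. Mitochondrial ribosomal proteins (32 of 67 up and 8 down, with 30 and 7 adjusted over the list alone, median 0.14) included RSM7 (0.98 ± 0.068). These lists had an adjusted p of 0.207 and 0.566 with an estimated correlation. Downward lists were cytosolic ribosomal proteins (102 of 128 down, the same adjusted over the list alone, median -0.14), purine biosynthesis (15 of 22 down and 4 up, the same adjusted over the list alone, median -0.26) and ergosterol synthesis (17 of 25 down and 2 up, the same adjusted over the list alone, median -0.25). Their adjusted p was 0.174, 0.128 and 0.321 with an estimated correlation, and ERG27 stood at -0.80 ± 0.063. Nuclear pore complex genes (19 of 33 down and 4 up, the same adjusted over the list alone, median -0.17), a list that holds NUP60, included MLP1 (-0.62 ± 0.076), and nuclear transport genes (21 of 40 down and 5 up, with 21 and 4 adjusted over the list alone, median -0.22) included KAP95 (-1.03 ± 0.063). Adjusted p stood at 0.546 and 0.466 with an estimated correlation. Without wild-type array 1 the nuclear pore, nuclear transport and mitochondrial ribosomal lists no longer passed (limma camera adjusted p = 0.0563, 0.0504 and 0.0763). Under quantile normalization the nuclear pore, pore-recruited and nuclear transport lists did not pass (0.077, 0.131 and 0.088), with medians of -0.16, 0.24 and -0.22. Nuclear pore, nuclear transport and G2/M genes lay 0.17, 0.070 and 0.13 higher in the median on wild-type array 1, and 0.14, 0.087 and 0.051 higher on array 3 labelled as the double deletion, than on the other arrays of these groups. Their medians were -0.15, -0.18 and 0.40 without both arrays. Among lists outside these, haploid-specific genes, phospholipid synthesis and glycolysis had a median, mean and test that differed in sign, and none of them passed.

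The effect of ADA2 deletion where NUP60 was also deleted was read from the arrays labelled as the double deletion against the nup60 arrays, a comparison that also differed in mating type and URA3. Besides the mating-type genes and URA3, ADA2 was at least 34.2-fold lower. The mating genes BAR1 (-3.91 ± 0.072, limma adjusted p = 1.71e-11), MFA2 (-3.88 ± 0.063) and MFA1 (-3.19 ± 0.074) fell. Their falls cannot be told apart from the difference in mating type. In this comparison 1806 genes rose and 1666 fell (63.7%), with 145 rises and 74 falls of at least 2-fold. Of the 45 lists 16 passed camera, 8 upward and 8 downward, and glucose-repressed carbon metabolism (28 of 34 up and 3 down, with 29 and 3 adjusted over the list alone, median 0.69) also passed with an estimated correlation (adjusted p = 0.0299). JEN1, a lactate transporter gene, rose by 1.81 ± 0.094. The respiratory chain (37 of 38 up, the same adjusted over the list alone, median 0.63) and the TCA cycle (16 of 16 up, the same adjusted over the list alone, median 0.47) shifted upward. For these lists the adjusted p became 0.141 and 0.148 with an estimated correlation. Seripauperin genes (10 of 13 up and 1 down, the same adjusted over the list alone, median 0.64), COS genes (7 of 9 up, with 7 and 1 adjusted over the list alone, median 0.51) and subtelomeric genes (127 of 227 up and 36 down, with 129 and 38 adjusted over the list alone, median 0.29) shifted upward too. These calls had an adjusted p of 0.141, 0.141 and 0.141 with an estimated correlation. Thiamine biosynthesis (12 of 16 up and 3 down, with 13 and 3 adjusted over the list alone, median 0.45) and the pheromone response (14 of 24 up and 3 down, with 16 and 3 adjusted over the list alone, median 0.33) had an adjusted p of 0.184 and 0.53 with an estimated correlation. The pheromone call was lost in fits chosen after seeing the data, without wild-type array 1 and array 3 labelled as the double deletion (limma camera adjusted p = 0.0636) and with a poly-A spike covariate (0.0953).

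Downward lists in this comparison were ribosome biogenesis (44 of 64 down, the same adjusted over the list alone, median -0.25) and a-specific genes (7 of 7 down, the same adjusted over the list alone, median -2.46). An estimated correlation gave an adjusted p of 0.141 and 0.141. Purine biosynthesis (13 of 22 down and 2 up, the same adjusted over the list alone, median -0.19) and cytosolic ribosomal proteins (71 of 128 down and 4 up, with 70 and 4 adjusted over the list alone, median -0.088) had an adjusted p of 0.141 and 0.296 with an estimated correlation. SAGA subunits (11 of 19 down and 1 up, the same adjusted over the list alone, median -0.17), iron regulon genes (15 of 31 down and 4 up, the same adjusted over the list alone, median -0.17) and ergosterol synthesis (13 of 25 down and 3 up, the same adjusted over the list alone, median -0.14) had an adjusted p of 0.141, 0.657 and 0.569 with an estimated correlation. The SAGA list holds ADA2, the gene whose deletion separates these groups, and was not tested without it. The SAGA, iron and ergosterol calls were each lost without nup60 array 3 (limma camera adjusted p = 0.0526, 0.0709 and 0.0638) and under quantile normalization (0.0689, 0.0854 and 0.194, with medians of -0.19, -0.19 and -0.13). The SAGA call was also lost without array 1 labelled as the double deletion (0.0561). The iron call was also lost without nup60 array 2 (0.0961) and without array 2 or 3 labelled as the double deletion (0.0658 and 0.0543). The ergosterol call was also lost without wild-type array 2 (0.0508), ada2 array 2 (0.0524) or array 3 labelled as the double deletion (0.0764), and with dim genes left out (0.0532). Without wild-type array 1 and array 3 labelled as the double deletion the iron and ergosterol calls were lost (0.0815 and 0.0773), and with a poly-A spike covariate the SAGA, iron and ergosterol calls (0.0953, 0.154 and 0.116). Among lists that did not pass here, the pore-recruited, multidrug, retrograde, haploid-specific, general stress, mitochondrial ribosomal, nuclear pore, unfolded protein and phosphate lists had a median, mean and test that differed in sign.

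The effect of NUP60 deletion where ADA2 was also deleted was read from the arrays labelled as the double deletion against the ada2 arrays, with the same difference in mating type and URA3. Besides the mating-type genes and URA3, YGR109W-A rose by 6.11 ± 0.15 (limma adjusted p = 1.42e-10), and NUP60 (-6.03 ± 0.091), ARO10 (-3.08 ± 0.10) and FET4 (-2.75 ± 0.12) fell. The a-factor gene MFA2 fell too (-3.30 ± 0.063), which cannot be told apart from the difference in mating type. In this comparison 1920 genes rose and 1845 fell (69.1%), with 286 rises and 79 falls of at least 2-fold. Of the 45 lists 27 passed camera, 16 upward and 11 downward, and 0 of them passed with an estimated correlation, where 16 lists had an unadjusted p below 0.05. The general stress response (60 of 63 up and 1 down, the same adjusted over the list alone, median 1.08), DNA damage genes (22 of 27 up and 2 down, the same adjusted over the list alone, median 0.35) and Hsf1 chaperones (16 of 25 up and 4 down, the same adjusted over the list alone, median 0.31) shifted upward. The adjusted p rose to 0.066, 0.066 and 0.0946 with an estimated correlation. DDR2 rose by 3.67 ± 0.088, HUG1 by 3.21 ± 0.073 and HSP42 by 2.22 ± 0.077. The respiratory chain (38 of 38 up, the same adjusted over the list alone, median 0.90), the TCA cycle (16 of 16 up, the same adjusted over the list alone, median 0.97) and glucose-repressed carbon metabolism (27 of 34 up and 4 down, with 27 and 5 adjusted over the list alone, median 0.60) had an adjusted p of 0.0964, 0.0971 and 0.066 with an estimated correlation. The pheromone response (19 of 24 up and 1 down, the same adjusted over the list alone, median 1.06), G2/M genes (15 of 19 up and 1 down, the same adjusted over the list alone, median 0.40) and cell wall genes (27 of 42 up and 6 down, the same adjusted over the list alone, median 0.31) had an adjusted p of 0.119, 0.167 and 0.251 with an estimated correlation. The proteasome (21 of 35 up and 1 down, the same adjusted over the list alone, median 0.16), mitochondrial ribosomal proteins (48 of 67 up and 2 down, the same adjusted over the list alone, median 0.25) and thiamine biosynthesis (12 of 16 up and 4 down, the same adjusted over the list alone, median 0.51) had an adjusted p of 0.12, 0.252 and 0.252 with an estimated correlation. Seripauperin genes (10 of 13 up and 1 down, the same adjusted over the list alone, median 0.53), COS genes (6 of 9 up, the same adjusted over the list alone, median 0.59) and subtelomeric genes (115 of 227 up and 44 down, the same adjusted over the list alone, median 0.24) had an adjusted p of 0.119, 0.0964 and 0.251 with an estimated correlation. Meiosis and sporulation genes (20 of 42 up and 6 down, with 19 and 6 adjusted over the list alone, median 0.26) had an adjusted p of 0.569 with an estimated correlation, and their median turned to -0.11 under quantile normalization.

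Downward lists against the ada2 arrays were ribosome biogenesis (54 of 64 down, with 55 adjusted over the list alone, median -0.43), cytosolic ribosomal proteins (66 of 128 down and 1 up, with 65 and 1 adjusted over the list alone, median -0.085) and purine biosynthesis (18 of 22 down, the same adjusted over the list alone, median -0.33). Adjusted p stood at 0.066, 0.251 and 0.066 with an estimated correlation. Gcn4-regulated genes (35 of 52 down and 7 up, the same adjusted over the list alone, median -0.22) included ARG3, which fell by 2.09 ± 0.099. With an estimated correlation this list had an adjusted p of 0.0946. The a-specific genes (5 of 7 down, the same adjusted over the list alone, median -1.26), histone genes (8 of 10 down and 1 up, the same adjusted over the list alone, median -0.27) and SAGA subunits (13 of 19 down, the same adjusted over the list alone, median -0.19) had an adjusted p of 0.213, 0.0964 and 0.0946 with an estimated correlation. Ergosterol synthesis (15 of 25 down and 3 up, the same adjusted over the list alone, median -0.17), the iron regulon (14 of 31 down and 7 up, the same adjusted over the list alone, median -0.18) and nuclear pore genes (13 of 33 down and 2 up, with 12 and 2 adjusted over the list alone, median -0.12) had an adjusted p of 0.364, 0.569 and 0.569 with an estimated correlation. The nuclear pore list holds NUP60, the gene whose deletion separates these groups, and was not tested without it. The iron, nuclear pore and meiosis calls were each lost without ada2 array 1 (limma camera adjusted p = 0.0734, 0.054 and 0.0771) or ada2 array 3 (0.0559, 0.0638 and 0.0537). Among the arrays labelled as the double deletion, leaving out array 1 or 2 removed the nuclear pore call (0.104 and 0.0636), array 2 or 3 the iron call (0.0708 and 0.0558) and array 3 the meiosis call (0.0623). The iron call was also lost without wild-type array 1 (0.0596) or 3 (0.0572). Under quantile normalization 5 lists no longer passed, namely iron, nuclear pore, meiosis, ergosterol and subtelomeric genes (0.0812, 0.115, 0.875, 0.089 and 0.105). Their medians were then -0.24, -0.14, -0.11, -0.18 and 0.062. Nuclear pore genes, which lay 0.14 higher in the median on array 3 labelled as the double deletion than on arrays 1 and 2, had a median of -0.17 without this array and wild-type array 1. With dim genes left out the nuclear pore, iron and meiosis calls were lost (0.0538, 0.0538 and 0.0737), and with arrays centred on their median the iron call (0.0696). Without wild-type array 1 and array 3 labelled as the double deletion the iron and meiosis calls were lost too (0.0769 and 0.0537), and a poly-A spike covariate removed the iron, ergosterol and meiosis calls (0.124, 0.0675 and 0.199). Phospholipid synthesis, which did not pass, had a median, mean and test that differed in sign.

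The interaction contrast asked whether the arrays labelled as the double deletion departed from the sum of both single deletions on the log2 scale. Of 5449 genes, 1124 lay above the sum and 1010 below it at a limma adjusted p below 0.05 (39.2%), of which 85 and 64 departed by at least 2-fold. The largest positive departures were those of MF(ALPHA)1 (9.16 ± 0.13), URA3 (8.50 ± 0.21), HMLALPHA1 (6.57 ± 0.17) and MF(ALPHA)2 (6.53 ± 0.15), and the largest negative ones were those of HMRA1 (-6.65 ± 0.10) and MFA2 (-3.51 ± 0.089). For these genes, as for every other gene, the contrast also held the difference in mating type and URA3. MF(ALPHA)1, URA3, HMLALPHA1 and HMRA1 had groups below background, so their values are fitted differences and no measure of size. Next came YGR109W-A (5.20 ± 0.21), ARG3 (-2.50 ± 0.14), ARO10 (-2.42 ± 0.15) and FMP48 (-2.38 ± 0.080). Across 4680 genes that passed against wild type, the slope of the double-deletion fold change on the sum of the single ones was 0.905. These genes include NUP60 and ADA2, whose falls were fixed by the deletions, and the mating-type genes and URA3, which departed from the sum. In 100 additive simulations the central 95% of slopes lay from 0.869 to 1.02.

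Of the 45 lists, 20 passed camera for the interaction, 10 above and 10 below the sum, and 0 of them passed with an estimated correlation, where 9 lists had an unadjusted p below 0.05. Respiratory chain genes (35 of 38 above, with 36 adjusted over the list alone, median 0.45) and TCA cycle genes (11 of 16 above, with 13 and 1 adjusted over the list alone, median 0.44) included NDE1 (1.29 ± 0.078) and ACO1 (1.19 ± 0.17). For these lists the adjusted p became 0.158 and 0.218 with an estimated correlation. The retrograde list (8 of 17 above and 2 below, with 8 and 3 adjusted over the list alone, median 0.25) included PDH1 (2.06 ± 0.070), at an adjusted p of 0.32 with an estimated correlation. Without wild-type array 1 and array 3 labelled as the double deletion its median was 0.12 and its call was lost (limma camera adjusted p = 0.0571), and with a poly-A spike covariate they were 0.027 and 0.0656. Seripauperin genes (10 of 13 above and 1 below, the same adjusted over the list alone, median 0.41), COS genes (4 of 9 above, the same adjusted over the list alone, median 0.44) and subtelomeric genes (86 of 227 above and 32 below, with 90 and 32 adjusted over the list alone, median 0.22) had an adjusted p of 0.15, 0.15 and 0.296 with an estimated correlation. Thiamine biosynthesis (9 of 16 above and 2 below, with 10 and 2 adjusted over the list alone, median 0.37) and G2/M genes (11 of 19 above and 2 below, with 12 and 2 adjusted over the list alone, median 0.30) had an adjusted p of 0.296 and 0.369 with an estimated correlation. The pheromone response (17 of 24 above and 1 below, with 19 and 1 adjusted over the list alone, median 0.85), haploid-specific genes (8 of 12 above and 1 below, the same adjusted over the list alone, median 0.44) and a-specific genes (7 of 7 below, the same adjusted over the list alone, median -1.43) had an adjusted p of 0.15, 0.337 and 0.15 with an estimated correlation, in arrays that differed in mating type and URA3. Pheromone, haploid-specific and G2/M genes lay 0.092, 0.11 and 0.13 higher in the median on wild-type array 1 and 0.074, 0.084 and 0.051 higher on array 3 labelled as the double deletion than on the other arrays of these groups. Without both arrays their medians were 0.73, 0.31 and 0.23.

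Below the sum were general stress genes (31 of 63 below and 10 above, with 32 and 10 adjusted over the list alone, median -0.25), with HSP12 at -2.17 ± 0.088 and SOL4 at -1.65 ± 0.11, although YGP1 lay above it (2.31 ± 0.17). For HSP12 and HSP26 the sum itself lies above the highest intensity in the values, 51828 on the linear scale. These genes could not reach it, so the departure of HSP12 is no measure of size. Purine biosynthesis (13 of 22 below and 2 above, the same adjusted over the list alone, median -0.23), the iron regulon (16 of 31 below and 5 above, with 17 and 5 adjusted over the list alone, median -0.32) and Gcn4-regulated genes (22 of 52 below and 9 above, with 23 and 9 adjusted over the list alone, median -0.15) were below the sum too. With an estimated correlation the adjusted p of these 4 lists was 0.292, 0.15, 0.541 and 0.229. Histone genes (6 of 10 below, with 7 adjusted over the list alone, median -0.19) and glycolysis (6 of 16 below, the same adjusted over the list alone, median -0.092) had an adjusted p of 0.15 and 0.188 with an estimated correlation. Ribosome biogenesis (23 of 64 below and 2 above, the same adjusted over the list alone, median -0.096) and cytosolic ribosomal proteins (18 of 128 below and 1 above, with 7 and 1 adjusted over the list alone, median -0.037) had an adjusted p of 0.369 and 0.581 with an estimated correlation. The G2/M call was lost without nup60 array 2 (limma camera adjusted p = 0.0564), ada2 array 2 (0.0682), or array 1 or 3 labelled as the double deletion (0.0504 and 0.0549). The call of cytosolic ribosomal proteins was lost without nup60 array 2 (0.0645) and under quantile normalization (0.178, with a median of -0.033). Iron regulon genes lay 0.14 and 0.059 lower in the median on wild-type array 1 and on array 3 labelled as the double deletion, and their median was -0.22 without both. Without wild-type array 1 and array 3 labelled as the double deletion the cytosolic ribosomal call was lost too (0.0642), and a poly-A spike covariate removed the iron, G2/M and cytosolic ribosomal calls (0.0595, 0.0595 and 0.158). Among lists that did not pass this test, the silencing, galactose, hexose, SUMO and proteasome lists had a median, mean and test that differed in sign.

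**Figure D3:**
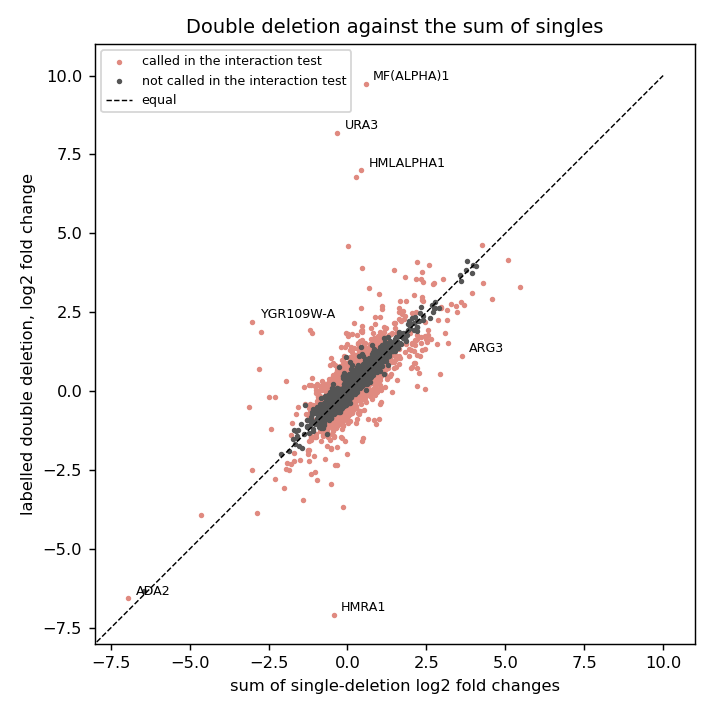
Log2 fold change against wild type in the arrays labelled as the double deletion (vertical axis) against the sum of the log2 fold changes of both single deletions (horizontal axis), with a point for each gene that passed in any comparison with wild type, red where the interaction test passed and grey where it did not, and a dashed line of equality. YGR109W-A lay 5.20 above the line, the departure of ARG3 was -2.50, and the positions of MF(ALPHA)1, URA3, HMLALPHA1 and HMRA1 rest on groups below background.

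As deletion strains can carry an extra or a missing chromosome, fold changes were also read by chromosome. By limma camera, 0 of 16 chromosomes shifted in each of the 3 comparisons with wild type, and 0 did at an unadjusted p below 0.05. The lowest unadjusted limma camera p values were 0.308, 0.143 and 0.212. Chromosome medians ranged from -0.049 to 0.007 in the nup60 arrays, from -0.039 to 0.037 in the ada2 arrays and from -0.052 to 0.09 in the arrays labelled as the double deletion. The highest median of an arm was 0.19.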

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

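The 3 tests of the mating type and URA3 described here were chosen only after the result was seen, and all other tests in this part were planned.

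The arrays labelled as the double deletion, which also differed in mating type and URA3, departed from the sum of the single effects for 2134 genes and 20 lists, by the interaction test of limma and camera. Of 100 splits of the 12 arrays, the real one alone, 1 split, gave as many genes, and the highest other count was 2119. As 95 of the other splits, which mix strains within a group and so widen the spread, gave 0 genes by limma, these splits say nothing on whether chance is excluded. At an unadjusted p below 0.05 the real count was 2634 and the highest other 2672. For lists, 22 of the 100 splits gave as many as the real 20, with a highest other count of 26. The mixed groups still differ in their share of each strain, so these list counts are no chance level and do not exclude chance.

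The genes picked out by that test were MF(ALPHA)1 (9.16), URA3 (8.50), HMLALPHA1 (6.57), MF(ALPHA)2 (6.53) and YGR109W-A (5.20) above the sum, and HMRA1 (-6.65), MFA2 (-3.51), ARG3 (-2.50), ARO10 (-2.42) and FMP48 (-2.38) below it, in log2 units. MF(ALPHA)1, URA3, HMLALPHA1 and HMRA1 had groups below background, so their values are fitted differences and no measure of size. Lists picked out above the sum were the pheromone response (median 0.851), respiratory chain (0.452), COS genes (0.444), haploid-specific genes (0.444), TCA cycle (0.436), seripauperins (0.406), thiamine (0.366), G2/M (0.298), retrograde (0.249) and subtelomeric genes (0.217). Those below it included a-specific genes (-1.428), iron (-0.324), general stress (-0.249), purine (-0.228), histones (-0.192), Gcn4 (-0.149), ribosome biogenesis (-0.096), glycolysis (-0.092) and cytosolic ribosomal proteins (-0.037).

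A signal in data outside the main measurement appeared in the control probe sets of reporter sequences. One of them, below background in wild type, was at least 685-fold higher in each of the nup60, ada2 and labelled double-deletion arrays, with fitted log2 differences of 10.36, 10.37 and 10.54. The labels name a kanamycin resistance marker in the same 9 arrays, and the sequence this probe set detects is not given in the sources used here. Another rose by 1.61, 1.75 and 2.80 in the same order. One, also below background in wild type, was at least 8.41-fold higher in the arrays labelled as the double deletion (fitted log2 difference 3.46). In these arrays one rose by 1.17, while one rose by 1.08 in the ada2 arrays, and one by 1.04 in the ada2 arrays and 1.24 in those labelled as the double deletion. The control probe sets for URA3 stood at 12.81, 12.47 and 12.31 for the 5' end, the middle and the 3' end in the arrays labelled as the double deletion. Of 388 probe sets without a gene name but above background, 54, 58 and 169 changed in the nup60, ada2 and labelled double-deletion arrays.

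Alpha-cell and URA3 transcripts in all 3 arrays labelled as the double deletion stood against the label, and 3 explanations were tested. A mixture with alpha URA3 cells that kept NUP60 and ADA2 is argued against, since ADA2 lay only 0.16 above its level in the ada2 arrays on the log2 scale. Loss of silencing of HML in MATa cells is argued against as well, since HMRA1 was at 4.38, below the background level of 5.62. The test of a strain of the other mating type with URA3 decides nothing, since the 11 of 11 a-specific and alpha-specific genes that moved that way against nup60 are the pattern itself. In their transcripts the arrays did stand as alpha cells with URA3, with HMRA1 at most 4.46 and HMLALPHA1 at least 11.64 on each. How they came to differ from the label stays open. Effects of mating type and URA3 on other genes cannot be separated from an interaction of both deletions with these arrays, and a biological interaction stays open.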

How the results depend on the processing

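The fit without wild-type array 1 and array 3 labelled as the double deletion, the poly-A spike covariate, and the removal of deleted genes, URA3 and mating lists were tests chosen only after the result was seen. Counts are given in the order nup60, ada2 and labelled double deletion against wild type, labelled double deletion against nup60 and against ada2, and interaction. With an estimated correlation between genes the lists that passed fell from 20, 18, 23, 16, 27 and 20 to 4, 1, 1, 1, 0 and 0, while 11, 8, 12, 12, 16 and 9 had an unadjusted camera p below 0.05, and the cause was not tested. No result reversed for the counts, for the 854 named-gene results, or for the 124 list calls, except in the median of meiosis and sporulation genes against ada2 (-0.114 under quantile normalization, a call lost at a camera adjusted p of 0.875), and the cause was not tested. Counts of genes at an adjusted p below 0.05 stayed within 1.5 times the principal ones under every alternative, while falls of at least 2-fold in nup60 went from 3 to 10 under quantile normalization. Leaving out each array gave 2284 to 3104, 2011 to 2768, 3810 to 4118, 3051 to 3777, 3460 to 4049 and 1642 to 2160 genes, and 19 to 21, 17 to 20, 21 to 25, 13 to 16, 24 to 27 and 18 to 23 lists. Of the 124 list calls, 18 were lost under quantile normalization, 11 with the poly-A covariate, 7 without both arrays, 4 without dim genes and 2 after centring, and leaving out an array lost 36 of 1488. Of 9852 refits of named-gene calls without an array, 121 lost the call. Without both arrays the gene counts were 3482, 3330, 4355, 3995, 4298 and 2634. Centring moved the share of positive calls from 52.7% to 42.7% for the interaction, from 49.7% to 57.8% for ada2 and from 51% to 44.9% for the labelled double deletion against ada2. Quantile normalization moved it from 48.9% to 42.6% for nup60, from 49.3% to 43.7% for the labelled double deletion, from 51% to 43.2% for the latter against ada2 and from 52.7% to 44.7% for the interaction. The correlation of the single deletions, 0.312, ranged from 0.304 without wild-type array 1 to 0.339 without wild-type array 2, and was 0.338 without deleted genes, URA3 and mating lists, and the cause was not tested. The slope, 0.905, ranged from 0.866 to 0.945 on leaving out an array. The replicate numbers did not pair the arrays, since 4 of 18 same-number pairs had a residual correlation over 0.1 (-0.726 to 0.367, median -0.04), and 2 arrays correlated best with their own number. With a replicate block the counts were 2548, 2209, 3854, 3252, 3620 and 1813 genes and 21, 19, 24, 16, 27 and 21 lists, with 13 named-gene calls and no list call lost. Signal over background limited folds of genes such as URA3 and MF(ALPHA)1 to lower bounds.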

Other observations

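The tests of messenger RNA yield and of scaling were chosen only after the result was seen, and the tests of degradation, of room to fall, of chromosome ends and of other splits were planned.

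The transcripts that rose at least 2-fold in the nup60 arrays were followed in the other deletions, which share the wild-type arrays, and no chance value was computed for the overlaps. Of these 142 genes, 42 were in the general stress list, 127 also rose at least 2-fold in the arrays labelled as the double deletion, 93 rose in the ada2 arrays and 16 fell there. Beyond the sum of both single effects, 157 genes rose in both single deletions and lay above the sum in the labelled double deletion. Among genes that departed from the sum, 308 of those above it and 222 of those below it had changed in neither single deletion, and 26 genes changed at least 2-fold in the labelled double deletion without passing in either single one.

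The rise near chromosome ends was tested for its reach, with the hypothesis that it may extend inward beyond the outermost 10 reading frames of each arm. In the arrays labelled as the double deletion the outermost 10 had a median of 0.302 (120 of 227 up and 48 down, camera adjusted p in limma of 0.000688, and 0.278 with an estimated correlation). Reading frames 11 to 20 had a median of 0.064 (109 of 288 up and 99 down, adjusted p 0.808), between the bounds of 0.05 and 0.1 set for the test, so the reach cannot be told apart from none by this value. Reading frames 21 to 30 and 31 to 40 had medians of -0.019 and 0.011. In the nup60 arrays the outermost 10 had a median of -0.010, and in the ada2 arrays 0.082.

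Wild-type array 1 and array 3 labelled as the double deletion deviated from their group means together, with a residual correlation of 0.733. Each ran against the other arrays of its group, at -0.87 and -0.881 in wild type and -0.857 and -0.781 in the labelled double deletion, although residuals from a mean of 3 always run against each other, at -0.485 to -0.522 in nup60 and -0.46 to -0.568 in ada2. Less messenger RNA relative to spike-ins and ribosomal RNA is a candidate explanation. Poly-A spikes, hybridisation spikes and ribosomal probe sets were higher on both arrays than on each other array of their group in 6 of 6 comparisons. Higher control signals are what this explanation states, and the test was chosen after the result was seen, so it does not decide the cause. Degraded RNA stays open, since the difference between 3' and 5' probe sets of control genes was 1.14 and 1.26 on these arrays and at most 1.06 elsewhere, a lead of 0.09 before rounding against the 0.3 that the test asked for. No biological explanation was tested, since the design gives none.

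Rises of at least 2-fold far outnumbered falls in the nup60 arrays, 142 to 3 (97.9%). The deleted gene NUP60 is one of the 3 falls. A scaling offset between arrays is argued against, since the share of rises was 97.3% after centring and 92.5% after quantile normalization (123 rises and 10 falls). No room to fall for genes near background is argued against too, since among 5071 genes well above background in wild type the share was 97% (98 rises and 3 falls). No biological explanation was tested for this difference.

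Other splits of the arrays gave fewer genes in the 5 comparisons of 3 with 3 arrays, where 10 splits are too few for a share under 0.05. For the nup60 arrays against wild type 1 split gave as many as the real 2798 genes, for ada2 1 split as many as 2491, for the labelled double deletion 1 split as many as 3991, against nup60 1 split as many as 3472 and against ada2 1 split as many as 3765. The highest other count was 0 in each by limma. Every other split mixes the strains within both groups, which widens the spread, so these counts of 0 say nothing on whether chance is excluded. At an unadjusted p below 0.05 the highest other counts were 447, 470, 878, 157 and 178, against real counts of 3132, 2890, 4090, 3641 and 3893. For lists, 2, 1, 3, 2 and 1 splits gave as many as the real 20, 18, 23, 16 and 27, and the highest other counts were 20, 17, 25, 18 and 23. The mixed groups still differ in their share of each strain, so the list counts of these splits are no chance level.

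Of 1746 probe sets of the second yeast, 63 passed in limma in the arrays labelled as the double deletion, all of them lower than in wild type. The median log2 fold change of all 1746 was -0.083 there, -0.040 in the nup60 arrays and 0.006 in the ada2 arrays.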
